A study of Homo sapiens with 12 samples.

How the data were processed

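Total RNA from 12 cultures of LNCaP, a prostate cancer cell line, was measured on expression arrays. Per the labels, the cells were transfected with miR-130a, miR-203, miR-205 or a scramble microRNA, with 3 arrays in each of the 4 groups, and the 3 arrays of a group are named biological replicates. The deposited table holds log2 values for 22277 probe sets on each array, and every column was mapped to a sample by its label. R 2.9.0, RMA and limma are named in the submitters' processing notes, with no role or order for each. The background method and the annotation behind the table are not given in the sources used here. The values start at 2.36 and reach 13.95, and the array medians lie between 2.76 and 2.78, so the 12 arrays share 1 scale. Between 29.6% and 31.6% of the probe sets of an array sit exactly at the lowest value, and 3023 probe sets sit there on all 12 arrays (4762 if values within 0.01 log2 of it are counted). The number of arrays (3 per group) limits the precision given here.

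Probe sets were named through the platform annotation supplied with the table. Of these, 19070 have 1 gene symbol, 1043 have several and 2164 have none, and only those with 1 symbol were used. The symbols of 19058 were found in the reference gene table (assembly GRCh38.p14), and 0 had to be changed. Each of the 11963 genes was represented by its probe set with the highest mean over all 12 arrays. A gene was tested if that probe set lay above the array's own median on at least 3 arrays, which left 6821 genes. Among these, 1425 genes (20.9%) have exactly equal values on some arrays of a group (3880 if values within 0.01 log2 are counted) and 262 have 3 equal values in a group where they are not dim, which narrows their measured spread. A gene not above the array median on any of a group's 3 arrays is given only as a bound, "at least N-fold": the mean of the brighter group against the mean, per dim array, of the higher of the array median and the gene's own value. A gene dim in both groups of a comparison has no fold.

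Differences were tested with limma 3.58.1 in R 4.3.3. A model of group means over all 12 arrays was fitted on the log2 values and moderated with eBayes (8 residual and 4.84 prior degrees of freedom), and each two-sided comparison was adjusted by Benjamini-Hochberg, with a threshold of 0.05. Differences are log2 values of the first group minus the second, with the standard error (SE) of the fit, and a moderated F-test covered any difference among the 4 groups. Gene lists were tested with camera from limma at a preset inter-gene correlation of 0.01, adjusted over the lists with at least 5 tested genes. The same test was run with a correlation estimated from the data. Members were counted by the gene-wise test over all genes and again adjusted over the list alone. The mean of each list per array was also compared among the groups by an exact permutation of the F statistic over all 15400 splits of the 12 arrays into 4 groups of 3. A comparison of 3 arrays with 3 has 10 splits, so an exact test of a single comparison cannot give p under 0.1. Array p-values measure the spread between these cultures.

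Before the data were examined, 28 gene lists were fixed, of which 24 had enough tested genes. They cover androgen-induced genes, nuclear receptor cofactors and chaperones, EGFR-RAS-MAPK components, ERK-induced genes, the PI3K-AKT-mTOR pathway, G2 and M phase genes, G1-S and DNA replication genes, p53 targets and interferon-induced genes. Others hold the unfolded protein and amino acid stress response, cholesterol synthesis, glycolysis and hypoxia, the mitochondrial respiratory chain, cytosolic ribosomal proteins, apoptosis regulators, the microRNA machinery, TGF-beta and BMP signalling, epithelial junctions, mesenchymal genes, and actin and focal adhesion. The last ones are described targets of each of the 3 microRNAs, written from general knowledge, and markers of luminal, basal and neuroendocrine prostate cells, fibroblasts and smooth muscle, and leukocytes and endothelium. Of 720 list genes, 615 were named on the arrays and the others were not analysed here. The named genes follow a rule fixed at the same time: per comparison with scramble, the 10 largest increases and 10 largest decreases past the threshold with no overlap between groups, up to 4 members of each list, the measured described targets, and 5 fixed genes, of which 4 were measured and 1 was not analysed here. The rule adds the 5 genes with the largest shared change and, between microRNAs, the 5 largest in each direction. The text names a part of these.

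Overlaps of calls between comparisons were set against n1 × n2 / N for independent lists and against 100 simulations of unchanged groups sharing the 3 scramble arrays. The procedure was tested on simulated data for the 6821 genes, with 0.5, 1 and 2 log2 added to known genes. For miR-130a against scramble it recovered 92.5% of genes shifted by 0.5, 98.5% of those shifted by 1 and 100% of those shifted by 2, and 2.02% of its calls were unchanged genes. For miR-203 these shares were 91.0%, 100%, 100% and 3.96%, and for miR-205 they were 92.5%, 100%, 100% and 4.41%. A simulated shifted list was called in 3 of 3 comparisons, and 0 of 66 unshifted lists were called. Genes were simulated as independent and without a floor, so this does not test list calls among correlated genes. In the real arrays the estimated correlation of the G2 and M phase list was 0.50 for miR-130a against scramble.

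The alternatives were no filter or a stricter filter on dim probe sets, 3 other scalings (quantile, median centring and cyclic loess), other choices of the probe set for a gene, a fit of only the 6 arrays compared, a trend in the prior variance, array weights, the replicate number as a block, stricter thresholds, all probe sets, fry in place of camera, and each array left out in turn. Leaving out genes with equal values was added after seeing the data. A planned comparison of genes with and without microRNA seed sites was not run, because the reference used here holds no 3′ UTR sequences. Figures were drawn with matplotlib 3.10.9 under Python 3.11.15.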

Results

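Gene expression was measured in LNCaP cells, an androgen-responsive prostate cancer line, after transfection with 1 of 3 microRNAs or with a scramble microRNA as control. The microRNAs were miR-130a, miR-203 and miR-205, each group including the control had 3 arrays (12 in all), and 6821 genes were bright enough to be tested. Each comparison with scramble asked which transcripts changed when that microRNA was transfected. Values are log2 differences ± SE of the limma fit over 3 arrays per group, unless a bound or another error is given. Arrays of 1 group correlated across genes with r between 0.996 and 0.999, arrays of different groups with r between 0.986 and 0.994, and no columns were identical. In all, 4149 genes (60.8%) differed among the 4 groups by the moderated F-test. The difference between 3′ and 5′ probe sets, a sign of RNA quality, overlapped between all groups for ACTB, with group means from 2.26 to 2.44 log2. For GAPDH it overlapped between scramble (0.56 to 0.90) and each microRNA group, while miR-203 arrays (0.74 to 0.80) lay above those of miR-130a (0.72 to 0.74, highest 0.737 against a lowest of 0.740) and miR-205 (0.60 to 0.73).

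**Figure D1:**
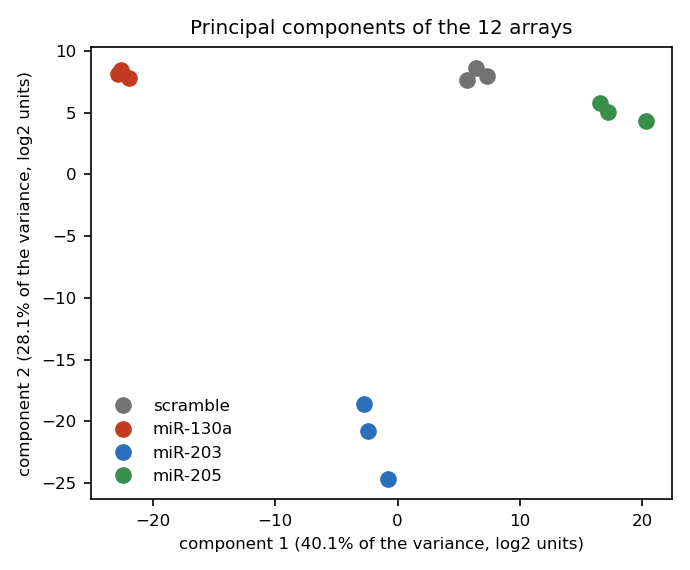
Principal components 1 and 2 of the log2 values of the tested genes, which hold 40.1% and 28.1% of the variance; each point is 1 array, coloured by group. The 3 arrays of each group lie together, with miR-130a apart on component 1 and miR-203 apart on component 2.

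Interferon-induced genes, whose products act against viruses, were higher in the miR-130a arrays than in scramble arrays. Of 28 members named on the arrays 23 were tested, of which 22 rose, 0 fell and 1 did not pass (22 rose adjusted over the list alone). The filter on brightness depends on the change here, since members dim in scramble arrays were tested because they were bright on other arrays. IFIT1, which binds viral RNA, rose by 6.73 ± 0.09, from 4.86 ± 0.12 (SD, n = 3) in scramble arrays to 11.60 ± 0.10 (SD, n = 3), with adjusted p = 6.66e-15. IFIT3 rose by 6.70 ± 0.12, OASL, of the oligoadenylate synthetase family, by 6.23 ± 0.13, and HERC5, a ligase for ISG15, by 5.31 ± 0.11. The antiviral RSAD2 and the RNA sensor RIGI were not above the array median on any scramble array and rose at least 38.4-fold and at least 34.7-fold. Likewise dim in scramble arrays were 3 chemokine genes, of which CXCL10 rose at least 146-fold, CCL5 at least 73.2-fold and CXCL11 at least 66.3-fold. The list's median change was 2.87 log2, and 2.87 with its 7 dim members at their bounds, with adjusted p = 2.87e-40 by camera and adjusted p = 0.00084 with an estimated correlation.

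Cell cycle genes were higher with miR-130a. Among G1-S and DNA replication genes, 16 of 30 rose and 0 fell (23 and 0 adjusted over the list alone), with MCM2, a subunit of the replicative helicase, up by 0.80 ± 0.10 and GINS1 up by 0.76 ± 0.14. Among G2 and M phase genes, 13 of 30 rose and 0 fell (16 and 0 adjusted over the list alone), including the mitotic kinesin KIF20A at 0.94 ± 0.16 and the kinase CDK1 at 0.72 ± 0.16. The G1-S list had a median of 0.41 and adjusted p = 6.73e-08 by camera, but adjusted p = 0.326 with an estimated correlation. For the G2 and M list these values were 0.48 and adjusted p = 9.52e-07, with adjusted p = 0.468 with an estimated correlation. MKI67, a proliferation marker, differed by 0.20 ± 0.11 and did not pass, with adjusted p = 0.189.

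Genes of the amino acid and unfolded protein stress response fell with miR-130a in 11 of 25 cases, rose in 2 and did not pass in 12, with the same counts adjusted over the list alone. ASNS, asparagine synthetase, fell by 1.51 ± 0.10, the glutathione-degrading CHAC1 by 1.45 ± 0.14 and the transcription factor DDIT3 by 1.39 ± 0.14. The list's median was -0.11 and its mean -0.37, with adjusted p = 0.00145 by camera and adjusted p = 0.19 with an estimated correlation. Other large decreases were PCK2, a mitochondrial phosphoenolpyruvate carboxykinase, at -1.63 ± 0.09, the cystine transporter SLC7A11 at -1.62 ± 0.09, TBL1XR1 at -1.36 ± 0.13 and DNAJC10 at -1.30 ± 0.12. NIBAN1 fell at least 2.93-fold and was above the array median on 0 miR-130a arrays.

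Cholesterol synthesis genes rose in 8 of 18 cases and fell in 2 (9 and 2 adjusted over the list alone), led by the methylsterol oxidase MSMO1 at 1.34 ± 0.08, HMGCS1 at 0.99 ± 0.07 and SQLE at 0.88 ± 0.11. The camera test gave a median of 0.19 with adjusted p = 0.000361, and adjusted p = 0.174 with an estimated correlation. Among apoptosis regulators 7 of 20 rose and 2 fell (8 and 2 adjusted over the list alone), with the pro-apoptotic PMAIP1 up by 2.30 ± 0.12 and the death receptors FAS and TNFRSF10B up by 1.17 ± 0.10 and 0.99 ± 0.07. Their median was 0.17 with adjusted p = 0.0194, and adjusted p = 0.175 with an estimated correlation. ERK-induced genes rose in 5 of 11 cases and fell in 0 (7 and 0 adjusted over the list alone), among them the phosphatase gene DUSP4 at 0.64 ± 0.11 and MCL1 at 0.45 ± 0.09. This list's median was 0.24, and 0.31 with 1 member at its bound, with adjusted p = 0.0347, and adjusted p = 0.175 with an estimated correlation.

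Of 11 measured genes described as miR-130a targets, 2 fell, 1 rose and 8 did not pass, also adjusted over the list alone. ATXN1 fell by 1.13 ± 0.14 (above the array median on 1 of 3 miR-130a arrays) and the kinase ROCK1 by 0.79 ± 0.08. DICER1, the enzyme that cuts microRNA precursors, rose by 0.85 ± 0.12 with adjusted p = 0.000219. The other 8, ACVR1, BMPR2, CYLD, INHBB, RAB5A, SMAD4, SMAD5 and TSC1, lay between -0.16 and 0.17, and the list gave adjusted p = 0.562 by camera. KLK3, which encodes prostate-specific antigen, fell by 0.28 ± 0.08 with adjusted p = 0.0206, and the cell cycle inhibitor CDKN1A differed by -0.04 ± 0.12 with adjusted p = 0.853. MSMB, a secreted prostate protein, was dim in scramble arrays and rose at least 3.85-fold.

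The remaining lists did not pass with miR-130a, with adjusted p from 0.148 to 0.866. Their members higher and lower were 8 and 3 of 27 androgen-induced genes (FKBP5 1.46 ± 0.15, ELL2 1.42 ± 0.17), 4 and 2 of 38 nuclear receptor cofactors and chaperones, 2 and 4 of 25 EGFR-RAS-MAPK components, and 5 and 3 of 19 p53 targets. The same counts were 1 and 2 of 20 for glycolysis and hypoxia, 0 and 0 of 28 for ribosomal proteins, 2 and 5 of 16 for the microRNA machinery, 2 and 0 of 21 for TGF-beta and BMP signalling, and 1 and 0 of 6 for mesenchymal genes. Luminal markers had 1 and 1 of 10, and described miR-203 targets had 4 and 2 of 16. All these counts were the same adjusted over the list alone. In other lists, adjusted over the list alone in brackets, the counts were 3 and 1 of 19 (2 and 0) for PI3K-AKT-mTOR, 0 and 4 of 27 (0 and 2) for the respiratory chain, 4 and 5 of 21 (4 and 6) for epithelial junctions, 4 and 2 of 29 (3 and 2) for actin and focal adhesion, and 5 and 2 of 19 (6 and 2) for described miR-205 targets.

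In total 1610 genes passed between miR-130a and scramble arrays, 819 higher and 791 lower (54.3% lower with quantile scaling), and 100 of them changed at least 2-fold, with dim genes at their bounds (76 higher and 24 lower). The arrays of both groups did not overlap for 2672 genes (39.2%), where chance gives 10%. The apoptosis call ended without scramble replicate 3 (adjusted p = 0.0597), and the ERK-induced call without scramble replicate 1 (adjusted p = 0.0992), without miR-203 replicate 1 (adjusted p = 0.0523) and under 4 other settings (adjusted p from 0.0528 to 0.169). KLK3 no longer passed without miR-130a replicate 1 (adjusted p = 0.0763) or 3 (adjusted p = 0.0571), without scramble replicate 2 (adjusted p = 0.0561) or 3 (adjusted p = 0.0754), or with its probe set of largest variance (adjusted p = 0.165). With no filter on dim probe sets the apoptosis median was 0.012 and the ERK-induced median 0.017, and with probe sets of largest variance the cholesterol median was 0.32 and the ERK-induced median 0.38. The stress median lay between -0.071 (without miR-130a replicate 2) and -0.19 (without genes with equal values), the cholesterol median at 0.47 without genes with equal values, and the apoptosis median at 0.26 without scramble replicate 1 and 0.096 without scramble replicate 3. With the mean of a gene's probe sets ELL2 was at 0.71, DICER1 at 0.40, DDC at -0.37, ACTA2 at 0.22 and ATXN1 at -0.67.

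**Figure D2:**
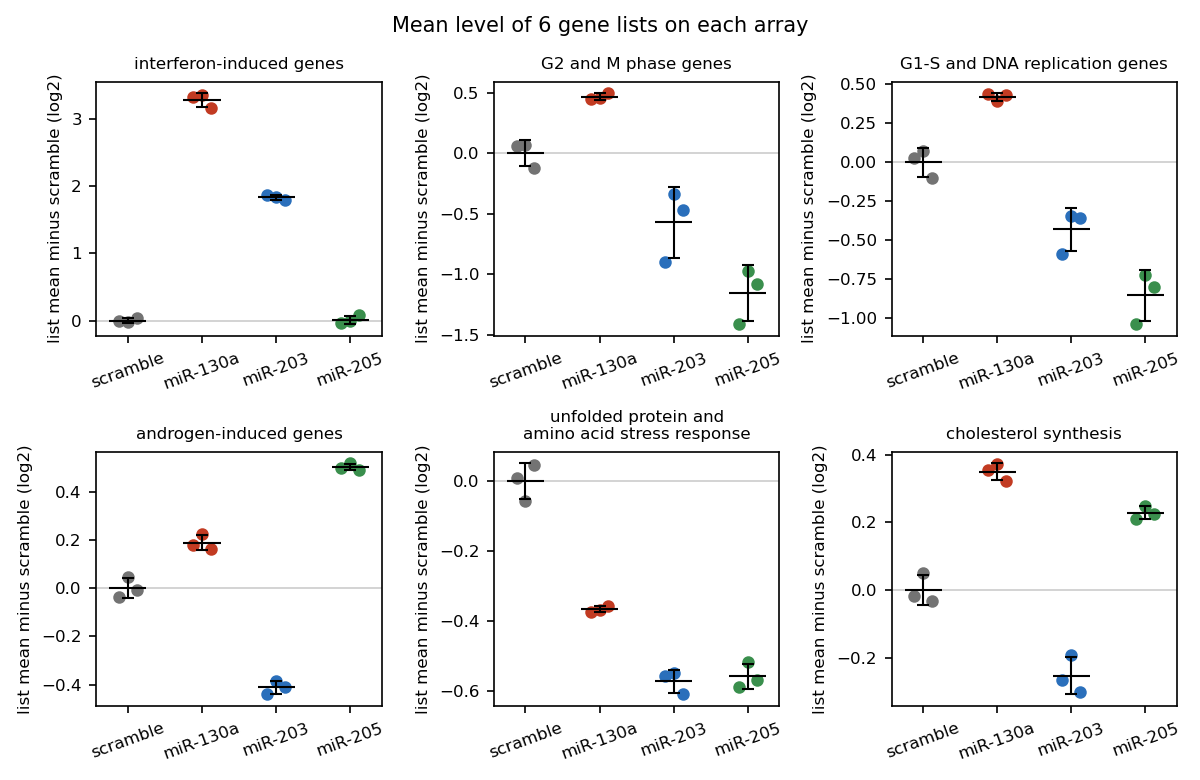
Mean log2 value of 6 gene lists on each array minus the mean of the scramble arrays; points are arrays, bars are group means and error bars are SD (n = 3). Interferon-induced genes lie far above scramble with miR-130a and miR-203, and the cell cycle lists lie above it with miR-130a and below it with miR-205.

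The arrays with miR-203 also showed higher interferon-induced genes, with 15 of 23 members up, 0 down and 8 not passing (21 up and 0 down adjusted over the list alone). IFIT1 rose by 4.81 ± 0.09 with adjusted p = 9.9e-13, IFIT3 by 4.39 ± 0.12, OASL by 4.15 ± 0.13 and HERC5 by 3.49 ± 0.11. CXCL10, CCL5 and OAS1, dim in scramble arrays, rose at least 11.6-fold, at least 6.44-fold and at least 6.56-fold. The list's median was 1.80, or 1.90 with 7 members at their bounds and any member dim in both groups left out. With no filter on dim probe sets it was 0.80 (adjusted p = 1.68e-17), and with the mean of a gene's probe sets 1.08 (adjusted p = 1.16e-15). By camera the list gave adjusted p = 2.02e-16, and adjusted p = 0.0192 with an estimated correlation.

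Androgen-induced genes fell with miR-203 in 15 of 27 cases and rose in 1, with the same counts adjusted over the list alone. The kallikrein KLK2 fell by 1.60 ± 0.11, the serine protease gene TMPRSS2 by 1.30 ± 0.11 and KLK3 by 1.24 ± 0.08 (adjusted p = 1.27e-07). The list's median was -0.34 with adjusted p = 4.44e-05, and adjusted p = 0.0384 with an estimated correlation. Stress response genes fell in 20 of 25 cases and rose in 0 (21 and 1 adjusted over the list alone), with the kinase-like TRIB3 at -1.28 ± 0.11, CHAC1 at -1.20 ± 0.14 and the secreted ER protein MANF at -1.11 ± 0.09. For this list the median was -0.48 with adjusted p = 4.17e-10, and adjusted p = 0.0237 with an estimated correlation.

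Cell cycle genes were lower with miR-203. In the G2 and M phase list 20 of 30 fell and 0 rose (22 and 0 adjusted over the list alone), with the spindle protein TPX2 at -1.24 ± 0.16 and CDC20, an activator of the anaphase-promoting complex, at -0.99 ± 0.19. In the G1-S list 19 of 30 fell and 0 rose (22 and 1 adjusted over the list alone), with the ribonucleotide reductase subunit RRM2 at -1.34 ± 0.15 and GINS2 at -0.86 ± 0.16. The medians were -0.55 and -0.44, with adjusted p = 1.81e-06 and adjusted p = 6.33e-06 by camera, and both lists had adjusted p = 0.33 with an estimated correlation. MKI67 fell by 0.58 ± 0.11 (adjusted p = 0.00099) and CDKN1A rose by 0.46 ± 0.12 (adjusted p = 0.00787). Those calls were lost with the MKI67 probe set of largest variance (adjusted p = 0.0923) and, for CDKN1A, in the fit of only the 6 arrays compared (adjusted p = 0.0509).

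Outside the lists, the largest decreases with miR-203 were COX6A1, a cytochrome c oxidase subunit, at -2.53 ± 0.13, CREBL2 at -2.03 ± 0.13, CPT1A, which brings fatty acids into mitochondria, at -1.98 ± 0.08, and the arginine transporter SLC7A1 at -1.90 ± 0.12. Of 16 measured genes described as miR-203 targets, 3 fell, 0 rose and 13 did not pass, and 1 fell adjusted over the list alone. The actin-binding LASP1 fell by 1.96 ± 0.10 (adjusted p = 3.41e-08), BIRC5 by 0.42 ± 0.15 (adjusted p = 0.0439) and BCL2L2 by 0.27 ± 0.09 (adjusted p = 0.0362). The other 13, among them ABL1, ATM, ROBO1 and SMAD4, did not pass, and the list gave adjusted p = 0.244 by camera. DICER1 rose by 0.54 ± 0.12 with adjusted p = 0.00338.

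Cholesterol synthesis genes fell in 6 of 18 cases and rose in 0, also adjusted over the list alone, with ACAT2 at -1.04 ± 0.11 and the regulator SREBF2 at -0.56 ± 0.09. TGF-beta and BMP signalling genes rose in 4 of 21 cases and fell in 1 (4 and 0 adjusted over the list alone), led by BAMBI, a decoy receptor that restrains this pathway, at 1.83 ± 0.09, and TGFBR3 at 1.06 ± 0.12. Their medians were -0.20 and 0.20 with adjusted p = 0.0348 and adjusted p = 0.0438, and each had adjusted p = 0.33 with an estimated correlation.

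The other lists did not pass with miR-203, with adjusted p from 0.0508 to 0.903. Counts higher and lower were 8 and 7 of 38 nuclear receptor cofactors and chaperones (MED1, of the Mediator complex, 1.36 ± 0.14), 4 and 1 of 11 ERK-induced genes, 2 and 1 of 19 PI3K-AKT-mTOR genes, 7 and 2 of 27 respiratory chain genes and 3 and 5 of 16 microRNA machinery genes. They were 0 and 3 of 6 for mesenchymal genes, 1 and 2 of 10 for luminal markers, 2 and 0 of 11 for described miR-130a targets and 4 and 4 of 19 for described miR-205 targets. These were the same adjusted over the list alone. In the rest, with the count adjusted over the list alone in brackets, they were 6 and 5 of 25 (6 and 7) for EGFR-RAS-MAPK components, 8 and 4 of 19 (9 and 4) for p53 targets, 3 and 4 of 20 (4 and 4) for glycolysis and hypoxia, 2 and 0 of 28 (0 and 0) for ribosomal proteins and 9 and 4 of 20 (11 and 4) for apoptosis regulators. They were 2 and 9 of 21 (3 and 9) for epithelial junctions and 3 and 11 of 29 (4 and 12) for actin and focal adhesion, where the tropomyosin gene TPM1 fell by 1.13 ± 0.09.

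Between miR-203 and scramble 2466 genes passed, 1177 higher and 1289 lower (48.5% lower with quantile scaling), and 172 changed at least 2-fold with dim genes at their bounds (58 higher and 114 lower). The groups did not overlap for 3019 genes (44.3%), where chance gives 10%. The cholesterol call ended without miR-203 replicate 3 (adjusted p = 0.0547), without scramble replicate 2 (adjusted p = 0.0566), with array weights (adjusted p = 0.0611) and with the probe sets of largest variance (adjusted p = 0.0594), and the TGF-beta call without the same arrays (adjusted p = 0.0544 and adjusted p = 0.0689) and under 3 other settings (adjusted p from 0.0717 to 0.106). BIRC5 lost its call without any 1 of the 3 miR-130a arrays, of miR-203 replicates 1 and 3, of miR-205 replicate 3 or of scramble replicates 1 and 2, and under 3 other settings (adjusted p from 0.0557 to 0.312), and BCL2L2 without miR-203 replicates 1 or 3 or scramble replicates 1 or 3, and under 3 other settings (adjusted p from 0.0745 to 0.121). The G2 and M phase median was -0.36 with array weights, the androgen-induced median -0.52 without genes with equal values, the TGF-beta median 0.12 with no filter on dim probe sets and 0.11 without scramble replicate 2, and the cholesterol median -0.12 without miR-203 replicate 3. Averaged over their probe sets, CPT1A was at -0.53, SLC7A1 at -0.65, TPM1 at -0.66, DICER1 at 0.24, DDC at -0.15 and ACTA2 at -0.16, and BIRC5 was at -0.18 with array weights.

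With miR-205, cell cycle genes fell. In the G2 and M phase list 27 of 30 fell, 0 rose and 3 did not pass (29 fell adjusted over the list alone), with CDC20 at -1.74 ± 0.19 (adjusted p = 2.5e-05), TPX2 at -1.61 ± 0.16 and the cyclin gene CCNB2 at -1.55 ± 0.22. In the G1-S list 25 of 30 fell and 0 rose (27 and 0 adjusted over the list alone), with the helicase subunit MCM5 at -1.64 ± 0.16, GINS2 at -1.34 ± 0.16 and thymidine kinase TK1 at -1.33 ± 0.15. The medians were -1.25 and -0.97 with adjusted p = 3.01e-18 and adjusted p = 9.9e-16 by camera. With an estimated correlation these calls were lost, with adjusted p = 0.185 for G2 and M and adjusted p = 0.171 for G1-S with an estimated correlation. By exact permutation over 15400 splits, the mean of either cell cycle list per array differed among the 4 groups with p = 6.49e-05 (adjusted p = 0.00039), the smallest p these splits can give. This permutation does not compare a list with other genes, and most fixed lists passed it. Ribosomal proteins and the respiratory chain had adjusted p = 0.0013 each. Only EGFR-RAS-MAPK components (adjusted p = 0.0946) and the microRNA machinery (adjusted p = 0.373) did not pass. MKI67 fell by 0.61 ± 0.11 with adjusted p = 0.000892.

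Androgen-induced genes rose with miR-205 in 18 of 27 cases and fell in 0 (19 and 0 adjusted over the list alone). The transcription factor MAF rose by 1.67 ± 0.09, FKBP5, a chaperone of steroid receptors, by 1.56 ± 0.15, the elongation factor ELL2 by 1.28 ± 0.17, and KLK3 by 0.56 ± 0.08 (adjusted p = 0.000165). The list's median was 0.39 with adjusted p = 8.2e-10, and adjusted p = 0.0118 with an estimated correlation. Other large increases were ANKRD46 at 1.96 ± 0.11, the histone gene H2BC21 at 1.57 ± 0.09, the growth hormone receptor GHR at 1.51 ± 0.13 and the cytokine signalling inhibitor SOCS2 at 1.33 ± 0.10.

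Stress response genes fell with miR-205 in 15 of 25 cases and rose in 0 (16 and 0 adjusted over the list alone), with CHAC1 at -1.90 ± 0.14, ASNS at -1.59 ± 0.10 and DDIT3 at -1.37 ± 0.14. The list's median was -0.45 with adjusted p = 4.61e-08, and adjusted p = 0.0523 with an estimated correlation. Interferon-induced genes did not pass as a list, with 2 higher and 3 lower of 23, also adjusted over the list alone, a median of 0.02 both with and without bounds, and adjusted p = 0.804. IFIT1 rose by 0.85 ± 0.09 and IFI35 fell by 1.16 ± 0.16 (above the array median on 2 of 3 miR-205 arrays).

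Cholesterol synthesis genes rose in 8 of 18 cases and fell in 3 (9 and 3 adjusted over the list alone), with MSMO1 at 1.08 ± 0.08 and LSS, lanosterol synthase, at 0.82 ± 0.08. Glycolysis and hypoxia genes rose in 8 of 20 cases and fell in 1, also adjusted over the list alone. Among them were NDRG1, also on the androgen-induced list, at 1.14 ± 0.11, the aldolase gene ALDOC at 0.63 ± 0.09 and the angiogenic factor VEGFA at -0.51 ± 0.07. TGF-beta and BMP signalling genes rose in 5 of 21 cases and fell in 1, also adjusted over the list alone, with ID2 at 0.96 ± 0.24. The medians were 0.15, 0.16 and 0.18, with adjusted p = 0.0185, adjusted p = 0.0185 and adjusted p = 0.0253. With an estimated correlation they had adjusted p = 0.273, adjusted p = 0.301 and adjusted p = 0.311.

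Of 19 measured genes described as miR-205 targets, 5 fell, 3 rose and 11 did not pass (6 fell and 3 rose adjusted over the list alone), and the list gave adjusted p = 0.629 by camera. CENPF, a kinetochore protein also on the G2 and M phase list, fell by 1.32 ± 0.17, HMGB3 by 0.58 ± 0.08 and VEGFA by 0.51 ± 0.07. MED1 rose by 0.88 ± 0.14, the laminin chain LAMC1 by 0.78 ± 0.13 and the receptor NOTCH2 by 0.46 ± 0.10. ERBB3, E2F1 and SRC differed by -0.22 ± 0.09, -0.35 ± 0.13 and -0.14 ± 0.12 and did not pass. HRAS, a GTPase of the RAS family, fell by 1.56 ± 0.11 (adjusted p = 7.99e-07), DICER1 rose by 0.76 ± 0.12 (adjusted p = 0.000439), and CDKN1A differed by 0.28 ± 0.12 (adjusted p = 0.0941).

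No other list passed with miR-205, with adjusted p from 0.0708 to 0.930. Their counts higher and lower were 6 and 3 of 25 EGFR-RAS-MAPK components, 3 and 2 of 11 ERK-induced genes, 5 and 4 of 19 PI3K-AKT-mTOR genes, 6 and 2 of 19 p53 targets (the stress cytokine GDF15 -1.45 ± 0.10), 3 and 5 of 27 respiratory chain genes and 0 and 1 of 28 ribosomal proteins. They were 2 and 3 of 20 for apoptosis regulators, 3 and 2 of 21 for epithelial junctions, 0 and 1 of 6 for mesenchymal genes, 1 and 2 of 10 for luminal markers and 1 and 3 of 16 for described miR-203 targets. These were the same adjusted over the list alone. With that count in brackets, they were 6 and 7 of 38 (7 and 7) for nuclear receptor cofactors and chaperones, 2 and 5 of 16 (3 and 5) for the microRNA machinery, 6 and 2 of 29 (7 and 2) for actin and focal adhesion and 4 and 1 of 11 (4 and 2) for described miR-130a targets.

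Between miR-205 and scramble 1781 genes passed, 771 higher and 1010 lower, and 151 changed at least 2-fold with dim genes at their bounds (23 higher and 128 lower). The groups did not overlap for 2657 genes (39.0%), where chance gives 10%. The glycolysis call ended without miR-205 replicate 2 (adjusted p = 0.0586), and the TGF-beta call without miR-205 replicate 1 (adjusted p = 0.114), without scramble replicate 2 (adjusted p = 0.0771), without a filter on dim probe sets (adjusted p = 0.0603) and with the mean of a gene's probe sets (adjusted p = 0.0685). ID2 no longer passed without miR-205 replicate 1 (adjusted p = 0.0553) or without a filter on dim probe sets (adjusted p = 0.0755). The glycolysis median was 0.10 without scramble replicate 1, and the TGF-beta median 0.11 with no filter on dim probe sets. Averaged over their probe sets, MAF was at 0.75, ELL2 at 0.65, GDF15 at -0.72, LSS at 0.46, VEGFA at -0.33, DICER1 at 0.38, CENPF at -0.50 and NOTCH2 at 0.16, and MKI67 was at -1.04 with its probe set of largest variance.

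**Figure D3:**
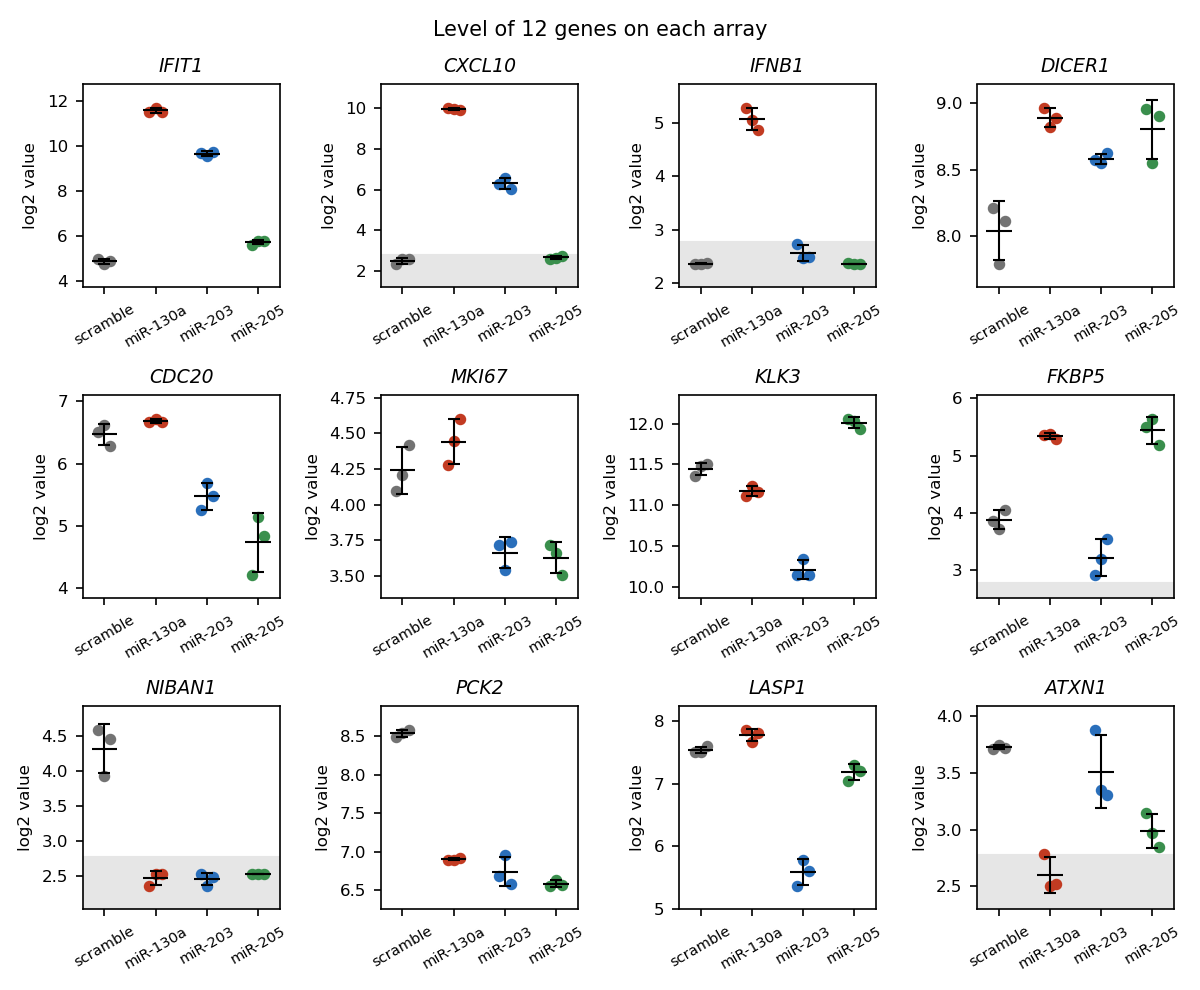
Log2 values of 12 genes on each array; points are arrays, lines are group means with SD (n = 3), and the grey area reaches up to the highest array median, where a level is only a bound. CXCL10 and IFNB1 lie in the grey area on the scramble arrays, and KLK3 is lowest with miR-203 and highest with miR-205.

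Markers of cell types other than luminal prostate cells were mostly dim. Of those named on the arrays, 0 of 16 leukocyte and endothelial, 2 of 11 basal, 3 of 17 neuroendocrine and 2 of 15 fibroblast and smooth muscle markers were bright enough to be tested, against 10 of 13 luminal markers. With miR-130a 1 of the 3 neuroendocrine markers, DDC, fell by 0.74 ± 0.08, ACTA2 of the fibroblast and smooth muscle list rose by 0.44 ± 0.11, and of the basal markers 0 passed. In miR-203 arrays 1 basal marker, ITGA6, rose by 0.25 ± 0.08 but was at -0.076 with its probe set of largest variance. There 2 neuroendocrine markers fell, TUBB3 by 0.31 ± 0.07 and DDC by 0.29 ± 0.08, and ACTA2 fell by 0.33 ± 0.11. With miR-205, 0 of these 7 tested markers passed. Adjusted over the list alone, these counts were the same except for 1 basal marker lower with miR-130a. The ACTA2 call with miR-130a ended without miR-130a replicate 3 (adjusted p = 0.0632) or without a filter on dim probe sets (adjusted p = 0.0602), and its call with miR-203 without any 1 of the miR-203 arrays, miR-130a replicate 1, miR-205 replicate 1 or scramble replicates 2 or 3, and under 3 other settings (adjusted p from 0.0502 to 0.119). The ITGA6 call ended without miR-203 replicates 1 or 2 or scramble replicates 1 or 2 (adjusted p from 0.0543 to 0.0829) and with the mean of its probe sets (adjusted p = 0.46), and the DDC call with miR-203 without miR-203 replicate 3 (adjusted p = 0.0517).

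Arrays with miR-130a were compared directly with those of miR-203 to test where the effects of these microRNAs differ. All 23 tested interferon-induced genes were higher with miR-130a, also adjusted over the list alone, and so were the chemokine genes CXCL11 by 4.69 ± 0.14, CXCL10 by 3.65 ± 0.12 and CCL5 by 3.51 ± 0.08. ULBP2, a ligand recognised by natural killer cells, was higher by 2.88 ± 0.11, and IFNB1, which encodes interferon beta, at least 4.94-fold, since it was above the array median on 0 miR-203 arrays. Lower with miR-130a were the splicing regulator PTBP2 at -2.10 ± 0.12, ZBTB43 at -1.74 ± 0.11, TSC22D3, which glucocorticoids induce, at -1.69 ± 0.09, the p53 target ZMAT3 at -1.56 ± 0.11, and BRDT, at least 2.56-fold lower. Androgen-induced genes were higher in 18 of 27 cases and lower in 2, with TSC22D3 among those 2 (19 and 2 adjusted over the list alone), with adjusted p = 0.0246 with an estimated correlation. Of 30 genes in each cell cycle list, 29 of G2 and M and 28 of G1-S were higher (29 and 29 adjusted over the list alone), with adjusted p = 0.268 and adjusted p = 0.169 with an estimated correlation. In all 2807 genes passed, 1437 higher and 1370 lower with miR-130a (56.2% lower with quantile scaling). TSC22D3 was at -0.96 with the mean of its probe sets, and the GAPDH 3′ and 5′ difference did not overlap between these groups (0.737 or less and 0.740 or more).

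Against miR-205, all 23 tested interferon-induced genes were again higher with miR-130a, also adjusted over the list alone, with IFIT3 at 6.61 ± 0.12. CXCL10, CCL5 and CXCL11, dim in miR-205 arrays, were at least 146-fold, at least 73.1-fold and at least 66.2-fold higher. Lower with miR-130a were MAF at -1.77 ± 0.09, the axon guidance gene SEMA6A at -1.60 ± 0.14, TBL1XR1 at -1.57 ± 0.13, ENDOD1 at -1.47 ± 0.08 and the adrenergic receptor gene ADRA2A at -1.45 ± 0.15. In both cell cycle lists 29 of 30 genes were higher and 0 lower, also adjusted over the list alone, with adjusted p = 0.14 for G2 and M and adjusted p = 0.0921 for G1-S with an estimated correlation. Androgen-induced genes were lower in 13 of 27 cases and higher in 1, also adjusted over the list alone, with adjusted p = 0.0921 with an estimated correlation. A total of 2293 genes passed, 1243 higher and 1050 lower (51.2% lower with quantile scaling). MAF was at -0.78 with the mean of its probe sets.

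Arrays with miR-203 and miR-205 differed in androgen-induced genes, of which 23 of 27 were lower with miR-203 and 1 was higher, also adjusted over the list alone, with adjusted p = 0.00314 with an estimated correlation. KLK2 was lower by -2.28 ± 0.11, FKBP5 by -2.22 ± 0.15, COX6A1 by -2.54 ± 0.13, APPBP2 by -2.24 ± 0.10 and CREBL2 by -2.09 ± 0.13. Interferon-induced genes were higher with miR-203 in 19 of 23 cases and lower in 0 (22 and 0 adjusted over the list alone), with IFIT3 at 4.30 ± 0.12, IFIT1 at 3.96 ± 0.09 and CXCL10 at least 11.6-fold, and with adjusted p = 0.00892 with an estimated correlation. Cholesterol synthesis genes were lower in 10 of 18 cases and higher in 0 (11 and 1 adjusted over the list alone), with adjusted p = 0.0359 with an estimated correlation. In total 2585 genes passed, 1432 higher and 1153 lower. APPBP2 was at -1.28 with the mean of its probe sets, and the GAPDH 3′ and 5′ difference did not overlap between these groups either (0.740 or more with miR-203, 0.732 or less with miR-205).

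Some genes moved the same way with all 3 microRNAs. PCK2 fell by 1.63 ± 0.09 with miR-130a, 1.79 ± 0.09 with miR-203 and 1.95 ± 0.09 with miR-205, and TRIB3 fell by 1.22 ± 0.11, 1.28 ± 0.11 and 1.28 ± 0.11. CHAC1 fell by 1.45 ± 0.14, 1.20 ± 0.14 and 1.90 ± 0.14, and NIBAN1 fell at least 2.93-fold, 2.95-fold and 2.95-fold. ANKRD46 rose by 1.62 ± 0.11, 1.36 ± 0.11 and 1.96 ± 0.11, and DICER1 was higher with each. In number, these were 126 genes higher and 173 lower in all 3 comparisons, where independent lists would give 16.0 and 22.1. Unchanged groups give 0 calls after adjustment, so a simulation of them does not test this count.

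Per pair, miR-130a and miR-203 shared 310 higher and 323 lower genes (141 and 149 if independent), miR-130a and miR-205 shared 235 and 259 (92.6 and 117), and miR-203 and miR-205 shared 291 and 455 (133 and 191). Genes past the threshold in opposite directions numbered 201, 179 and 176 (291, 211 and 320 if independent). Across genes, which are not independent replicates, the fold changes correlated with r = 0.43, 0.16 and 0.35, where unchanged groups against the same scramble arrays gave 0.50. By ranks the correlations were 0.25, 0.24 and 0.37 against a simulated 0.48, so the most similar pair was then miR-203 and miR-205. The covariances were 0.0732, 0.0225 and 0.0473 against a simulated 0.00571, a difference of 0.0675, 0.0168 and 0.0416. Only 3 scramble arrays were used, too few to split, so part of the excess of shared genes over independent lists may come from the shared controls.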

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

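Every test of an explanation in this part was chosen after the result was seen, except the exact permutation of the cell cycle list means and the other splits of the arrays, which were fixed before.

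The effects of the microRNAs differed between groups by a direct test of the difference for the following lists, given as the median log2 difference with limma's camera, and for 3 fixed genes. Between miR-130a and miR-203 arrays these were androgen-induced genes at 0.56, G2 and M phase genes at 1.03, G1-S genes at 0.81, interferon-induced genes at 1.47, stress response genes at 0.15, cholesterol synthesis at 0.40, the respiratory chain at -0.19, ribosomal proteins at -0.13 and actin and focal adhesion at 0.18. KLK3 differed by 0.96, CDKN1A by -0.50 and MKI67 by 0.78. Between miR-130a and miR-205 arrays they were androgen-induced genes at -0.16, G2 and M phase genes at 1.72, G1-S genes at 1.40, interferon-induced genes at 2.70 and glycolysis and hypoxia at -0.18, with KLK3 at -0.84, CDKN1A at -0.32 and MKI67 at 0.82. Between miR-203 and miR-205 arrays they were androgen-induced genes at -0.77, G2 and M phase genes at 0.65, G1-S genes at 0.44, interferon-induced genes at 1.15, cholesterol synthesis at -0.44 and actin and focal adhesion at -0.19, with KLK3 at -1.80. With its 5 dim members at their bounds, the interferon median between miR-203 and miR-205 was 1.53. With an estimated correlation, 8 of these list differences passed: interferon-induced genes in all 3 comparisons, androgen-induced genes and cholesterol synthesis in both comparisons with miR-203, and actin and focal adhesion between miR-203 and miR-205.

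Interferon-induced genes rose with miR-130a and miR-203. The tables argue against immune or endothelial cells in the cultures, since 0 of 16 of their markers lay above the array median on any array and the largest rise of one was 0.13 log2. They also argue against a single array, since the list median stayed at 1.72 or more in miR-203 and 2.80 or more in miR-130a with any array left out. An equal response of the list to any transfected microRNA is argued against too. The list mean was 3.65 log2 in miR-205 arrays and 3.64 in scramble arrays. By camera the list differed between miR-203 and miR-205 with adjusted p = 0.00892 with an estimated correlation. IFIT1 did rise with miR-205, so a weaker response of some members there is not excluded. Interferon beta made by the cells may contribute with miR-130a, where IFNB1 lay above the array median on 3 of 3 arrays. Its mean there (5.07 ± 0.21 log2, SD, n = 3) was at least 4.95-fold that of scramble. With miR-203 IFNB1 differed by 0.20 log2 and lay under the array median on all 3 arrays, which leaves this open. Whether the cells sensed the transfected material or lost microRNA targets cannot be told apart, because the labels give 1 microRNA name per group and no further sequence of it.

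Amino acid and unfolded protein stress genes were lower than scramble with all 3 microRNAs, but with miR-130a only 11 of 25 fell while 2 rose and 12 did not pass. With an estimated correlation the list had adjusted p = 0.19 with miR-130a, 0.0237 with miR-203 and 0.0523 with miR-205. By list mean, each scramble array lay at 7.38 log2 or more and each of the 9 other arrays at 7.08 or less. The exact permutation of this mean gave p = 0.00455, the smallest that 220 splits can give. The list was picked because it was lower than scramble in all 3 comparisons. This p therefore does not exclude chance deviations of the shared scramble arrays. A single scramble array is argued against as the source of the lower list median, which stayed at -0.091 or lower without any 1 of them. The largest adjusted p was then 0.00235 by camera at the preset correlation. These fits were not run with an estimated correlation, so they do not secure the call with miR-130a. A raised level in the scramble arrays remains a candidate explanation: over the list the microRNA groups differed by 0.33 log2 on average among themselves and by 0.57 from scramble, and it cannot be told apart from a shared microRNA effect without untransfected arrays.

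Cell cycle lists moved in opposite directions with miR-130a and miR-205. With an estimated correlation the G2 and M phase list had adjusted p = 0.468 and 0.185 in these comparisons and the G1-S list 0.326 and 0.171. Under 3 other scalings the G2 and M phase median stayed at 0.46 or more in miR-130a and at -1.24 or lower in miR-205. The median of all genes moved to 0.03 at most. The array medians of the deposited table already lay between 2.76 and 2.78, so a further scaling could hardly turn the list medians. These scalings do not test the submitters' own normalization, and no conclusion on it is drawn. Array-to-array variation unrelated to the groups is argued against by the exact permutation p = 6.49e-05, the smallest that 15400 splits can give. An effect of each microRNA on proliferation is a hypothesis these values leave open, and so are density or growth conditions common to the 3 cultures of a group, which the values do not separate from the microRNA.

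For the counts of genes, each comparison of 3 arrays with 3 has 10 splits, too few for a share under 0.05. In each of the 6 comparisons 1 of 10 splits, the real one, reached its count (1610, 2466, 1781, 2807, 2293 and 2585), and the highest other gave 0. For the gene lists the splits are also too few: with miR-130a the real split gave 7 lists and the highest other 6 (1 of 10 as large), with miR-203 it gave 7 and the highest other 8 (2 of 10 as large), and with miR-205 it gave 7 and the highest other 6 (1 of 10 as large). At the preset correlation a mixed split thus gave 1 list more than the real one with miR-203 and 1 fewer with the others, while all mixed splits gave 0 genes. For any difference among the 4 groups, 1 of 100 splits of the 12 arrays, the real one, reached 4149 genes, and the highest other gave 1698. This share is under 0.05 and argues against chance, though it is the smallest that 100 splits can give. For the 299 genes shared by all 3 microRNAs, 3 of 100 splits, the real one among them, gave as many, a share under 0.05. The highest other gave 568, so some mixed groupings of these arrays share more genes than the real one. With this few drawn splits the share is imprecise, so chance is not firmly excluded for this count.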

How the results depend on the processing

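Leaving out genes with equal values was the only setting chosen after the results were seen. Over all settings, the named genes kept their result in 8255 cases, lost their call in 316, gained it in 10 and reversed in 1. This was ITGA6 with miR-203, -0.076 with its probe set of largest variance against 0.25, and the cause was not tested. The gene lists kept their result in 1771 cases, lost their call in 37, gained it in 61 and reversed in 0. A kept result includes genes and lists that passed in neither setting. Only 7 of 24 lists passed in each comparison with scramble, and 16 list calls were lost with an estimated correlation. Signal over background limits these arrays, since a gene near the lowest value gives only a bound.

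Counts of genes moved by over 1.5 times under these settings, by their construction as stricter thresholds or more tests. Asking for at least 1.5-fold as well, on fitted values, gave 434 (miR-130a), 720 (miR-203) and 517 (miR-205) genes against scramble, 953, 730 and 798 between microRNAs (miR-130a with miR-203, miR-130a with miR-205, miR-203 with miR-205), and 58 shared by all 3. Adjusted p under 0.01 gave 899, 1594 and 1034 against scramble, 1513 (miR-130a with miR-205), 1703 (miR-203 with miR-205) and 139 shared. All probe sets gave 3815 (miR-203), 2696 (miR-205), 4321, 3500 and 3985 between microRNAs, and 6419 by the F-test. Lists past the threshold were 1, 3 and 1 of 24 with an estimated correlation, 16 (miR-130a) and 19 (miR-203) with fry, which does not compare a list with other genes, and 11 (miR-203) both with no filter on dim probe sets and with a trend in the prior variance; for the last ones the cause was not tested.

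With each array left out in turn, genes ranged over 1182 to 1729 (miR-130a), 2091 to 2470 (miR-203) and 1304 to 1927 (miR-205) against scramble, 2352 to 2864, 1839 to 2438 and 2107 to 2635 between microRNAs, 210 to 334 shared by all 3 and 3760 to 4156 by the F-test. Lists ranged over 6 to 7, 5 to 10 and 6 to 8. Without genes with equal values the counts against scramble were 1470, 2265 and 1661. No scaling moved the split of higher and lower calls by over 10 points, but in 4 comparisons the larger side turned. Quantile scaling took the share of lower calls from 49.1% to 54.3% (miR-130a against scramble), 52.3% to 48.5% (miR-203 against scramble), 48.8% to 56.2% (miR-130a against miR-203) and 45.8% to 51.2% (miR-130a against miR-205). Median centring turned it for miR-130a against scramble (52.9%) and against miR-203 (51.0%), so which side is larger there is not settled.

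The replicate numbers were not taken to pair the arrays, since not every same-numbered pair correlated over 0.1, which does not exclude a pairing. Deviations from the group means of same-numbered arrays correlated at -0.11 to 0.31, over 0.1 in 3 of 18 pairs. Those of other-numbered arrays of different groups correlated at -0.28 to 0.16. Of 12 arrays, 9 correlated best with their own number, a hint from the data and not the design. With the replicate block the counts against scramble were 1631, 2486 and 1751, no list changed its call, and 4 named genes lost and 1 gained theirs.

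No seed site comparison was run, since no 3′ UTR sequences were used here.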

Other observations

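The lists and genes in this part were all chosen after the results were seen. No p of a list is given, since the lists were written after some of their members were seen to change, and the counts only describe the genes.

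Amino acid uptake and synthesis genes were lower with each microRNA. Of 16 listed 14 were tested, of which 10 fell and 0 rose with miR-130a, 9 fell and 1 rose with miR-203, and 10 fell and 0 rose with miR-205, at medians of -0.56, -0.66 and -0.62. The glutamine transporter SLC1A5 fell by 1.04 ± 0.10, 0.75 ± 0.10 and 0.92 ± 0.10 (log2 ± SE, n = 3), and the mitochondrial folate enzyme MTHFD2 by 0.78 ± 0.08, 0.63 ± 0.08 and 1.17 ± 0.08. Of 16 tested cytosolic aminoacyl-tRNA synthetases (20 listed), which charge tRNAs with amino acids, 9 fell and 2 rose, 7 fell and 0 rose, and 11 fell and 1 rose, with GARS1 at -1.01 ± 0.09, -1.39 ± 0.09 and -1.31 ± 0.09.

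Of 18 chemokine and NF-kB-induced genes 7 were bright enough to be tested, and of these 7 rose with miR-130a, 3 with miR-203 and 1 with miR-205. The filter on brightness depends on the change here, since genes dim in scramble arrays, such as CXCL10, CCL5, CXCL11 and TNFAIP3, were tested because they were bright on other arrays. The NF-kB inhibitor NFKBIA rose by 0.79 ± 0.11 with miR-130a, and TNFAIP3, which restrains NF-kB, at least 3.38-fold. Of 11 tested class I antigen presentation genes (16 listed), 5 rose and 0 fell with miR-130a, among them the peptide transporter TAP1 at 0.76 ± 0.16 and B2M at 0.44 ± 0.10, while 0 rose and 4 fell with miR-205, among them the peptidase ERAP1 at -1.03 ± 0.11. With miR-203 2 were higher and 0 lower. Of 8 tested histone genes (19 listed), 5 rose and 0 fell with miR-203, led by H2BC21 at 1.82 ± 0.09 and H2BC5 at 0.86 ± 0.12, while 2 rose and 0 fell with miR-130a, and 1 rose and 2 fell with miR-205.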
